A study of Mus musculus with 8 samples.

How the data were processed

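Total RNA of 8 cultures of a mouse KP lung tumour cell line was extracted with a column kit, per the labels' protocols, and sequenced, 1 library per culture. The deposited files hold whole-number counts per Ensembl gene, 1 file per library, with 48526 genes and 5 summary lines each, and the counts were not normalized by the authors. The submitters' processing notes name CASAVA, STAR, Picard, HTSeq, DESeq2, bedtools and R 3.3.0, and the builds mm10 and GRCm38; which step used which tool, the annotation release, the strand setting and the library kit are not given in the sources used here. The summary lines are those HTSeq writes. They stayed out of library sizes and tests. Of the entries in a file, 56.97% to 61.72% were counted in genes and 26.48% to 30.53% were alignments to several places, which were not counted, so near-identical paralogs (Serpina1 genes, histone genes) are undercounted and their split is uncertain. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart.

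Gene symbols and coordinates came from GENCODE M21 on GRCm38, the build the notes name, though possibly another release than the authors counted with. Of the 48526 identifiers, 48058 had a symbol. Groups came from the genotype labels. No pair of libraries agreed within sampling noise, so all 8 entered as separate samples. Library totals in genes ran from 24160720 to 28073609, and 26163 genes had a count in any library.

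The test of all genes was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts: filterByExpr with the group, TMM scaling, robust dispersion and quasi-likelihood fits, and Benjamini-Hochberg adjustment over the 13770 genes tested, with a threshold of 0.05. Adjusted p-values in the text come from that test unless another is named. CPM values are counts scaled to the TMM-adjusted library size, means are given ± SD over 4 libraries, and log2 fold changes are KO over Control ± SE. The biological coefficient of variation was 21.6%. Where a gene had no count in a group, a bound was computed with 3 counts over the group, and where it had 1 to 12, a ratio of counts with a 95% exact interval; both cover counting error only, since reads without molecular identifiers are not independent molecules.

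The 31 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 for the 28 lists with at least 5 tested genes, adjusted over lists, and each list's members were counted past the threshold over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Chromosomes and Reactome sets of 10 to 300 tested genes (from fgsea 1.28.0) were tested with camera in the same way. The genes named are Asf1a, its paralog Asf1b and Csf2; the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups' libraries and a symbol that is not a predicted gene or pseudogene; up to 4 members of each described list with the smallest p; and tested genes within 1 Mb of Asf1a. Dnmt3a, the histone genes Hist1h4j and Hist1h4k, and Ube2e2, Ifi27l2b and Dicer1, neighbours of lost genes, were named after their values were seen. So were the genes that a plot shows as lost in all KO clones.

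The pipeline was tested on simulated counts drawn from the real means and dispersions, 4 against 4 libraries. In them 67 genes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Camera found a gene set raised 1.5-fold in both runs, and did not call an unchanged set in either. Means and dispersions carry no correlation between genes, so these simulated sets cannot check camera's preset correlation. In the data, estimated correlations of the lists that passed ran from 0.069 (senescence) to 0.763 (G2/M). With equal spread in both groups, the pipeline was run on 13598 genes. It recovered 11.9% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 87.9% of those changed 4-fold, with 7.0% of its calls on unchanged genes. With a larger spread in the KO group, run on 13616 genes, the shares were 23.9%, 53.7% and 92.4%, with 3.2% of calls on unchanged genes.

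The alternatives were DESeq2 1.42.0, limma-voom, voom with group quality weights, RLE size factors, library totals alone, no low-count filter, a filter of CPM above 1 in at least 4 libraries, a threshold of 0.01, each library left out in turn, and the 6 libraries numbered 1 to 3 with and without their number as a block. Fits with chromosome medians removed and without chromosome 12 genes were added after seeing the data. No library was left out of the main comparison.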

Results

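RNA of cultured KP cells was sequenced. KP cells are a mouse lung tumour line with an activated Kras gene and no functional p53, and the parent of all lines here was a single clone that expresses Cas9. Asf1a is a histone chaperone that carries H3-H4 dimers to the assembly of chromatin. Of 8 libraries, 4 came from Asf1a KO cells and 4 from cells wild type for Asf1a. Each KO library came from 1 clone, picked after editing with 1 of 4 Asf1a guides and numbered here KO clone 1 to 4. Control libraries 1 to 3 carried control guides and control library 4 the vector alone, and these were described as lines, not as picked clones, so that clonal origin and the KO group coincide. All lines were selected with blasticidin at 5 µg/ml. The libraries held between 24160720 and 28073609 reads counted in genes, and 13770 genes had enough counts to be tested. Each guide or vector gave 1 library, so the p-values below measure the spread between these lines and treat them as independent.

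The question of the design was how loss of Asf1a changes the transcripts of these tumour cells, and Asf1a itself comes first. Its transcript (ENSMUSG00000019857, chromosome 10, 53596757 to 53609225, GRCm38) was not lower as a group: 24.5 ± 14.3 CPM in the KO clones and 24.6 ± 1.42 CPM in the control libraries (SD, n = 4 each), a log2 fold change of -0.004 ± 0.385 (SE, adjusted p = 0.996). The clones themselves ranged widely, at 7.69, 21.4, 42.2 and 26.7 CPM in KO clones 1 to 4, whereas the control libraries lay between 22.5 and 25.8 CPM. A Cas9 frameshift need not lower the count of a gene's reads, so these counts alone do not check the KO label. Its paralog Asf1b, the form expressed with cell division, had a log2 fold change of -0.33 ± 0.19 (SE, adjusted p = 0.343). The tested genes within 1 Mb of Asf1a were Cep85l, Mcm9, whose annotated span overlaps Asf1a, and Man1a, with log2 fold changes of 0.32, -0.02 and -0.65 and adjusted p of 0.754, 0.944 and 0.233.

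Csf2 was higher in the KO clones. It encodes the myeloid growth factor GM-CSF. It was named in advance as the gene this study is known for, so its rise here is not an independent finding. Its level (chromosome 11, 54247271 to 54249667) was 10.7 ± 2.66 CPM in the KO clones against 4.04 ± 0.579 CPM in the control libraries, a 2.64-fold rise (log2 1.40 ± 0.22 SE, adjusted p = 0.00967), and each KO clone lay above each control library.

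**Figure D1:**
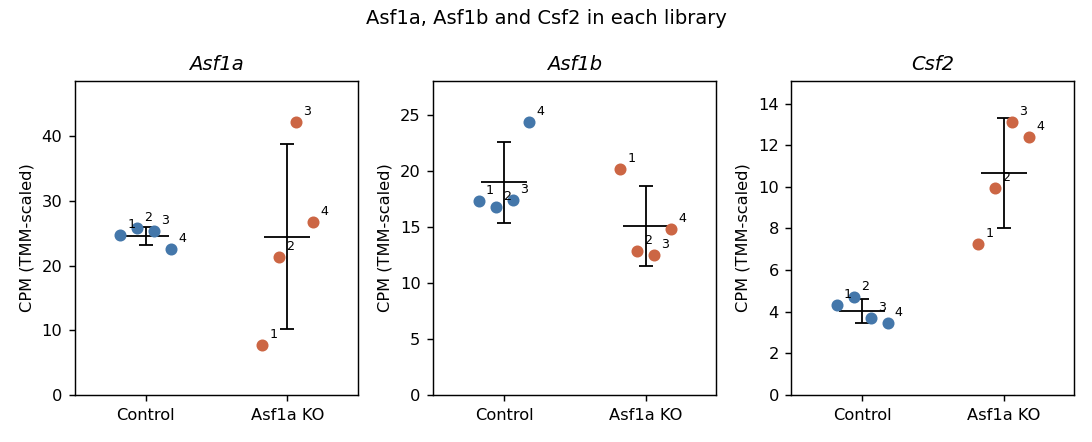
CPM of Asf1a, Asf1b and Csf2 in each library, with TMM scaling; points are libraries with their number, the bar is the group mean and whiskers are 1 SD (n = 4). KO clone 1 holds 7.69 CPM of Asf1a and KO clone 3 holds 42.2 CPM, while Csf2 in the KO clones averages 10.7 CPM and lies above the control libraries.

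Across all genes, 723 of 13770 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 409 higher and 314 lower in the KO clones. Of these, 321 changed at least 2-fold, 161 upward and 160 downward. In 707 of the 723 genes the 4 KO clones and the 4 control libraries did not overlap; among all tested genes this held for 14.4%, where chance gives 2.86%. The count rested on each library: 1901 genes passed without KO clone 1, 1461 without KO clone 2, 452 without KO clone 3 and 369 without KO clone 4, and 150, 317, 162 and 195 without control libraries 1 to 4. DESeq2 called 1623 genes, and 721 of the 723 were among them. The excess of higher genes did not hold throughout: limma-voom called 349 higher and 381 lower, and a fit with no low-count filter 336 and 401. Lower genes were also more numerous without control libraries 1 to 4 (65 and 85, 134 and 183, 77 and 85, 88 and 107) and without KO clone 2 (728 and 733). Of the 78 genes past the threshold that are named by the rule in the methods, 35 kept their call in all 8 fits that left out 1 library.

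Of the 10 genes with the largest rises, 9 had a control mean under 2 CPM. Slc28a1, a nucleoside transporter, rose from 0.231 ± 0.121 to 5.29 ± 4.25 CPM (log2 4.51 ± 0.64 SE, adjusted p = 0.00642). Nrep, a neuronal regeneration related protein, was the exception and rose from 23.5 ± 3.07 to 157 ± 44.8 CPM (log2 2.74 ± 0.23 SE, adjusted p = 4.57e-04). The protein arginine deiminase gene Padi1 rose by 3.11 on the log2 scale and the casein gene Csn3 by 2.71. These 4 genes kept their call without any 1 of the 8 libraries. Tspan32, Hoxa3, the R-spondin receptor gene Lgr5, the calcium channel Trpv6, Greb1 and Pde4b rose by 4.28, 3.67, 2.96, 2.83, 2.69 and 2.58 on the log2 scale, with adjusted p between 0.0119 and 0.0446. The call of Trpv6 ended without control library 3 (adjusted p = 0.0517) and those of Tspan32 and Lgr5 without control library 1, 3 or 4 (up to 0.0994), Lgr5 also without KO clone 4. Those of Hoxa3, Pde4b and Greb1 ended whichever control library was left out (up to 0.142), Greb1 also without KO clone 3 or 4.

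The largest falls were near-complete losses. The Serpina1 genes, which encode alpha-1-antitrypsin, form a cluster on chromosome 12 between 103728156 and 103958975. Serpina1a, Serpina1b, Serpina1d and Serpina1e together with Serpina1c held 2 to 6 reads in each KO clone and between 1464 and 12718 reads in each control library. Serpina1b, the most abundant, averaged 172 ± 104 CPM in the control libraries and had 10 reads over the 4 KO clones (ratio 1850, 95% counting interval 1010 to 3860). Serpina1c had no read in any KO clone and 1357 in the control libraries, at least 454-fold lower with a floor of 3 counts over the group. These paralogs are near-identical and their annotated spans overlap, so the split of reads among them is uncertain, while their sum does not depend on it. Control library 2 held 60.4 CPM of the 5 genes together, against 225 to 451 CPM in the other control libraries. With quality weights per group in limma-voom, Serpina1a, Serpina1b, Serpina1d and Serpina1e no longer passed (adjusted p between 0.115 and 0.166), and Serpina1c did not without a low-count filter (adjusted p = 0.0609).

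Genes outside that cluster were lost as well. Ago1 (chromosome 4, 126435012 to 126468583), an Argonaute protein of the microRNA pathway, averaged 20.4 ± 4.27 CPM in the control libraries and had 4 reads over the 4 KO clones (ratio 540, interval 211 to 1990, adjusted p = 1.03e-05). Tut4 (chromosome 4, 108459426 to 108559421), a terminal uridylyltransferase that acts on the let-7 precursor, averaged 8.17 ± 2.07 CPM and had 2 reads (ratio 431, interval 119 to 3570, adjusted p = 7.11e-05). The zinc finger genes Zfp37 and Zfp532 and the cholinesterase gene Bche fell from 391, 464 and 280 reads over the control libraries to 2, 3 and 1, ratios of 201 (interval 55.2 to 1660), 159 (54 to 773) and 287 (51.2 to 11400). Counting intervals cover counting error only. The calls of the Serpina1 genes and of these 5 genes held without any 1 library.

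**Figure D2:**
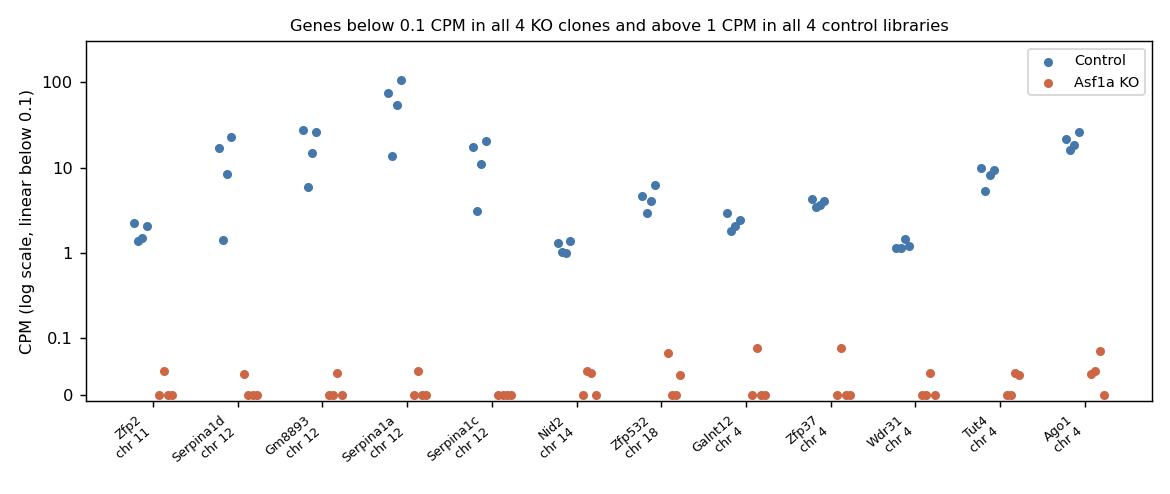
CPM of the 12 genes that lie below 0.1 CPM in all 4 KO clones and above 1 CPM in all 4 control libraries, 1 point per library, on a log axis that is linear below 0.1. Control values of Serpina1a run from 13.5 to 105 CPM.

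Replication-dependent histone genes, which supply H1, H2A, H2B, H3 and H4 to replicating DNA, were higher in the KO clones. Of 68 listed members 15 had enough counts to be tested. Of these, 11 rose and 0 fell, and 13 rose when p was adjusted over the list alone. Hist1h4j and Hist1h4k averaged 0.178 and 0.157 CPM in the control libraries and 1.41 and 0.997 CPM in the KO clones. Such members reach the tests through their KO counts, which favours rises in the list's count and median. The median log2 fold change was 1.63. Hist1h2bc rose from 27.3 ± 4.04 to 111 ± 36.5 CPM (4.07-fold, adjusted p = 0.00222) and Hist2h2be from 12 ± 0.248 to 36.5 ± 11.9 CPM (3.04-fold, adjusted p = 0.00391). Hist1h2bg and Hist1h2be rose 5.13-fold and 5.08-fold from levels under 1 CPM. These 4 kept their calls without any 1 library, and the list's mean log2 ratio to the control mean was 1.01, 1.47, 1.43 and 2.08 in KO clones 1 to 4. The list passed camera with a preset correlation (adjusted p = 9.19e-13) and fry (adjusted p = 0.00509), and missed with an estimated correlation (adjusted p = 0.399 with an estimated correlation). Histone paralogs share sequence, and multi-mapped reads were not counted.

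Neither the chaperone partners of Asf1a nor the replacement histones changed in that way. Of 26 genes for H3-H4 chaperones and ASF1 partners, none passed in edgeR and none in DESeq2, and 1 had an unadjusted p under 0.05, Mcm2 at a log2 fold change of -0.41 (adjusted p = 0.195). The H3.3 chaperone gene Hira had a value of 0.17 (adjusted p = 0.353). Of 9 replacement histone genes none passed in edgeR, 1 had an unadjusted p under 0.05 and 1 passed in DESeq2; the smallest p was that of H3f3b, at -0.31 (adjusted p = 0.0816).

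Cholesterol biosynthesis genes were lower. Of 24 tested members, 16 fell and 0 rose, 19 fell over the list alone, and the median log2 fold change was -0.66. Acat2, which makes acetoacetyl-CoA, fell from 84.2 ± 3.08 to 26.6 ± 5.66 CPM (3.17-fold, adjusted p = 6.69e-04), Mvd from 73.5 ± 5.87 to 28.2 ± 7.24 CPM (2.60-fold, adjusted p = 0.00341) and Dhcr7, the last enzyme of the pathway, from 76.6 ± 2.56 to 32.9 ± 7.03 CPM (2.33-fold, adjusted p = 0.00333). Lss, the lanosterol synthase gene, fell 1.80-fold (adjusted p = 0.00707). All 4 kept their calls without any 1 library. The list passed camera with a preset correlation (adjusted p = 5.2e-15) and fry (adjusted p = 0.0132), not camera with an estimated correlation (adjusted p = 0.481 with an estimated correlation).

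**Figure D3:**
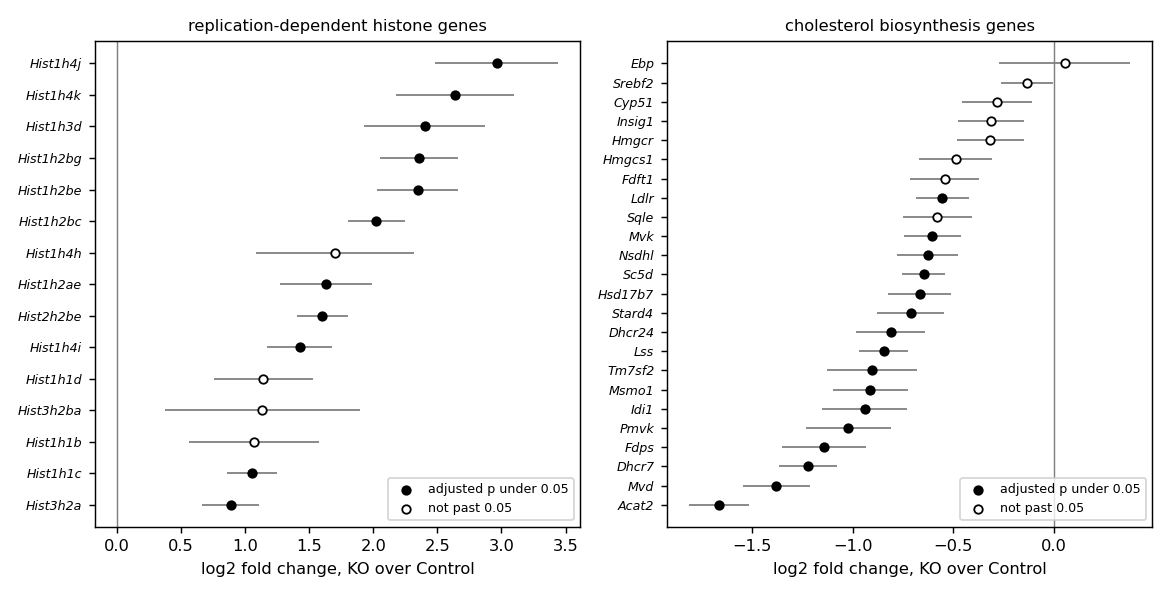
Log2 fold change of each tested replication-dependent histone gene (left, 15 genes) and cholesterol biosynthesis gene (right, 24 genes), KO over Control, with its standard error; filled points passed an adjusted p of 0.05. The histone genes lie to the right of 0 (11 passed) and 23 of the 24 cholesterol genes to the left (16 passed).

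Gene sets not chosen by hand held the same pathway. Of 789 Reactome sets, 7 were higher and 29 lower with a preset correlation. The cholesterol biosynthesis set (22 genes, 14 fell) had a median of -0.64 (adjusted p = 7.51e-11), and the SREBP activation set (23 genes, 10 fell) a median of -0.49 (adjusted p = 1.74e-07). Sets that hold ribosomal protein genes made up most of the lower ones. In the translation elongation set, 4 of 86 genes fell and the median was -0.36 (adjusted p = 5.89e-12). Higher sets included collagen fibril assembly (6 of 26 genes rose, median 0.46, adjusted p = 9.08e-05), anchoring fibrils (3 of 11, median 0.79, adjusted p = 4.61e-04) and degradation of the extracellular matrix (8 of 56, median 0.29, adjusted p = 0.0129), and the DNA methylation set (5 of 11, median 0.72, adjusted p = 7.21e-04), in which 4 of the 5 were histone genes and the other was Dnmt3a. Other lower sets included amino acid synthesis (3 of 16 fell, median -0.35, adjusted p = 3.3e-04), fatty acyl-CoA biosynthesis (2 of 16, median -0.28, adjusted p = 0.00739) and initiation of mitochondrial translation (4 of 80, median -0.09, adjusted p = 0.0221). With an estimated correlation 0 of the 789 sets passed (18 at an unadjusted p under 0.05), the smallest adjusted p being 0.993. Without KO clone 1, 79 sets passed in place of 36.

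The immune lists did not pass in the main test. Of 46 TNF and NF-kB target genes, 4 rose, 1 fell and the list had an adjusted p of 0.916; 11 rose and 2 fell over the list alone. Besides Csf2, the gp130 cytokine gene Clcf1 rose 1.53-fold (adjusted p = 0.0290) and the sphingosine kinase gene Sphk1 rose 3.26-fold (adjusted p = 0.0299), while Il1a fell 3.78-fold from 0.660 ± 0.190 CPM (adjusted p = 0.0190). Of 33 cytokines, chemokines and growth factors that act on myeloid cells, 2 rose and 4 fell (4 and 5 over the list alone, list adjusted p = 0.490, median 0.04, mean -0.08). The chemokine genes Ccl17 and Cxcl15 fell 4.53-fold from 1.49 ± 0.534 CPM and 5.37-fold from 3.87 ± 1.54 CPM (adjusted p = 0.00957 and 0.0135). The calls of Csf2, Ccl17 and Cxcl15 held without any 1 library; those of Clcf1, Sphk1 and Il1a ended in 5, 6 and 4 of the 8 such fits, each without control library 1, 3 or 4 among them, with adjusted p of up to 0.110.

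Of 34 type I interferon response genes, 1 rose and 1 fell, over the list alone as well (list adjusted p = 0.916, median 0.17, though the list test pointed downward): Ifi27 rose 1.37-fold and Ifi27l2a fell 3.96-fold. Ifi27 lies on chromosome 12, and with chromosome medians removed its log2 fold change was 0.09 in place of 0.45 (adjusted p = 0.695). The interferon list had a mean log2 ratio of 0.92 in KO clone 2 and of -0.39, -0.56 and -0.27 in KO clones 1, 3 and 4, and without KO clone 2 the list was lower (median -0.25, adjusted p = 0.0157, within 0.0157 to 0.996 over its alternatives). Of 17 MHC class I genes none passed in edgeR or DESeq2, 1 passed in limma-voom and 2 had an unadjusted p under 0.05 (list adjusted p = 0.168). That list had a mean log2 ratio of -0.42, -0.53 and -0.50 in KO clones 1, 3 and 4 and of 0.15 in KO clone 2, and passed at an adjusted p of 0.00347 without KO clone 2 and of 0.0287 without a low-count filter, within a range of 0.00347 to 0.767 over its alternatives. H2-K1, a classical MHC class I heavy chain, stood at 1.81, 10.2, 3.09 and 1.20 CPM in KO clones 1 to 4 against 14.3 ± 2.51 CPM in the control libraries (adjusted p = 0.0997). Of 18 immune checkpoint ligands and related surface proteins, 2 rose and 2 fell (3 and 3 over the list alone, list adjusted p = 0.490): Cd276 rose 1.36-fold and Vtcn1 rose 4.59-fold, while Tnfsf4 fell from 82 to 9 reads (ratio 9.35, interval 4.69 to 21.2) and Tnfrsf14 from 63 to 9 reads (ratio 7.19, interval 3.55 to 16.4). The 6 calls of single genes in this paragraph ended without control library 1, and in at least 1 more of the 8 fits without 1 library, with adjusted p of up to 0.15.

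Cell cycle genes were lower as lists and not as single genes. Of 48 genes of G1/S and DNA replication, none passed (7 at an unadjusted p under 0.05, 2 in DESeq2), the median was -0.18 and the list had an adjusted p of 6.09e-04 (adjusted p = 0.767 with an estimated correlation). Of 50 G2/M genes none passed (3 at an unadjusted p under 0.05, 0 in DESeq2), with a median of -0.26 and an adjusted p of 8.67e-04 (adjusted p = 0.767 with an estimated correlation). KO clone 1 lay at 0.16 and 0.24 in these lists' mean log2 ratios, above the control mean, and KO clones 2 to 4 between -0.26 and -0.55. Control library 4 lay at 0.20 and 0.45 and control library 2 at -0.09 and -0.36, so the groups overlap. The G2/M list no longer passed without KO clone 3 or without control library 4 (adjusted p up to 0.211).

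Genes tied to senescence were lower as a list (24 genes, 1 rose, 3 fell, 1 and 5 over the list alone, adjusted p = 0.0213, and adjusted p = 0.481 with an estimated correlation). Igfbp5, an insulin-like growth factor binding protein, fell from 132 ± 4.49 to 26.5 ± 4.96 CPM (4.97-fold, adjusted p = 6.65e-05) and kept its call without any 1 library. Cdkn2a, the p16 and p19Arf locus, fell 1.42-fold (adjusted p = 0.0171), Il1a is given above, and the matrix protease gene Mmp14 rose 1.52-fold (adjusted p = 0.0354). The list's call ended without KO clone 3 or control library 4 (adjusted p up to 0.159). Of 26 p53 target genes, 2 rose and 1 fell, over the list alone as well (list adjusted p = 0.570). Pmaip1, the pro-apoptotic Noxa gene, fell from 8.26 ± 1.11 to 1.44 ± 0.602 CPM (5.75-fold, adjusted p = 0.00333), and Plk2 and Mdm2 rose 1.69-fold and 1.28-fold (adjusted p = 0.0253 and 0.0318). The calls of Cdkn2a, Mmp14, Plk2 and Mdm2 ended without control library 1, 3 or 4, among others (adjusted p up to 0.136), and that of Pmaip1 held.

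Immediate early genes were higher as a list (23 genes, 2 rose, 0 fell, 7 and 1 over the list alone, median 0.39, adjusted p = 0.00944, and adjusted p = 0.481 with an estimated correlation). Klf10 rose 1.40-fold (adjusted p = 0.0284) and Dusp1, a MAP kinase phosphatase gene, rose 1.89-fold (adjusted p = 0.0433); Ccn2 had a log2 fold change of 0.83 (adjusted p = 0.0510). Mesenchymal genes were also higher (20 genes, 3 rose, 1 fell, 9 and 1 over the list alone, median 0.45, adjusted p = 0.0204, and adjusted p = 0.481 with an estimated correlation). That list's mean log2 ratio was 0.526, 0.286 and 0.418 in KO clones 1, 3 and 4. In KO clone 2 it was -0.216, below the control libraries (-0.102 to 0.077). The collagen genes Col1a1 and Col6a1 rose 2.05-fold and 1.63-fold, the integrin gene Itga5 rose 1.80-fold, and the receptor kinase gene Axl fell 1.39-fold. The mesenchymal call ended without KO clone 1 (adjusted p = 0.196), and the calls of these 6 genes ended whichever control library was left out, among others (adjusted p up to 0.162). Of 24 KRAS and MAPK output genes, 2 rose and 0 fell, over the list alone as well (list adjusted p = 0.689), Lif and Phlda1, 1.43-fold and 1.36-fold. Both calls ended whichever control library was left out and without KO clone 3 or 4 (adjusted p up to 0.165).

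Lists of adhesion, lineage and developmental genes did not pass in the main test, though some did under alternatives. Of 27 basement membrane and integrin genes, 3 rose and 1 fell (9 and 2 over the list alone, adjusted p = 0.214, in DESeq2 0.0424): the tenascin gene Tnc rose from 6.26 ± 1.48 to 29.2 ± 13.2 CPM (4.67-fold, adjusted p = 0.00840) and the nidogen gene Nid2 fell from 121 to 2 reads (ratio 62.1, interval 16.8 to 519). Of 24 epithelial genes, 2 rose and 1 fell (4 and 2 over the list alone, adjusted p = 0.490). Of 19 gastrointestinal and embryonic lineage genes, 1 rose and 2 fell, over the list alone as well (adjusted p = 0.214); Runx2, a transcription factor of advanced KP tumours, rose 1.70-fold (adjusted p = 0.00545) and Hnf4a fell 1.75-fold (adjusted p = 0.0304). Of 15 alveolar type II and lung genes, Cxcl15 alone passed, over the list alone as well (list adjusted p = 0.168). Of 100 listed developmental transcription factors that Polycomb represses in stem cells, 21 had enough counts to be tested. Of these, 4 rose and 0 fell (4 and 1 over the list alone, adjusted p = 0.0535), among them Hoxa5 with a 6.32-fold rise to 1.08 ± 0.460 CPM (adjusted p = 0.0136). Members that are low in the control libraries reach the tests through their KO counts, which favours rises here as among the histone genes. The Polycomb list was higher in DESeq2 (adjusted p = 0.016), with RLE factors (0.0384), without control libraries 1 to 4 (0.0252, 0.0355, 0.0234 and 0.0243) and without KO clone 1 (4.75e-04), in a range of up to 0.562. It did not pass in its other alternatives, among them the fit with no low-count filter. Its mean log2 ratio was -0.45 in KO clone 1 and 0.52 to 0.89 in the others. Of 19 imprinted genes, Peg13 and Blcap rose 1.74-fold and 1.61-fold (adjusted p = 0.00421 and 0.00650; list adjusted p = 0.114), and no other member passed over the list alone. The imprinted list passed without KO clone 1 (adjusted p = 0.016), without control library 3 (0.0397) and with chromosome medians removed (0.0341), in a range of up to 0.481. The calls of Tnc, Nid2, Runx2, Peg13 and Blcap held without any 1 library, while those of Hnf4a and Hoxa5 ended without control library 1 or 3, among others (adjusted p up to 0.101).

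Of 37 stress response genes, 1 rose and 1 fell (3 and 3 over the list alone, adjusted p = 0.490), and of 36 hypoxia and glycolysis genes 1 rose and 2 fell, over the list alone as well (adjusted p = 0.168, passing in DESeq2 at 0.0287, without KO clone 2 at 0.0411 and without control library 2 at 0.0379, in a range of up to 0.767); Aldoc, an aldolase gene, fell 2.67-fold (adjusted p = 0.00222). In edgeR no gene passed among 10 mitochondrially encoded genes (0 at an unadjusted p under 0.05, 0 in DESeq2, list adjusted p = 0.214), 5 genes of the 2-cell-like state (2 and 2, 0.961) and 4 germline genes (2 and 2, too few for the list test; 2 fell over the list alone). The mitochondrial list passed as higher without control library 2 (adjusted p = 0.0154, in a range of up to 0.767). The 2-cell-like list passed as higher in DESeq2 (adjusted p = 8.41e-05), with no low-count filter (0.00377) and without KO clone 1 (0.0131), in a range of up to 0.998. Markers of other cell types were mostly absent: of 25 leukocyte, 16 endothelial and 19 fibroblast and pericyte markers, 6, 5 and 2 had enough counts to be tested. No leukocyte or endothelial marker passed (1 and 2 at an unadjusted p under 0.05, 0 and 1 in DESeq2, list adjusted p of 0.336 and 0.503), and 1 endothelial marker rose over the list alone. Both fibroblast markers rose, Gsn 1.76-fold (adjusted p = 0.00972) and Col1a1, which the mesenchymal list also holds. The call of Gsn ended without control library 1 (adjusted p = 0.0566).

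Whole chromosomes differed between the KO clones and the control libraries. Chromosome 12 stood out: its genes had a median log2 ratio to the control mean of 0.20, 0.45, 0.48 and 0.34 in KO clones 1 to 4, and of at most 0.04 in size in the control libraries. Of its 451 tested genes 90 rose and 8 fell (camera adjusted p = 3.03e-22, and adjusted p = 0.519 with an estimated correlation). The few Y-linked genes were lower in each clone, with medians of -0.43, -0.61, -0.39 and -0.46; of 4 listed Y genes Kdm5d, Ddx3y and Uty fell 1.75-fold, 1.66-fold and 1.32-fold, and all 4 over the list alone. The call of Uty ended when any 1 control library, KO clone 3 or KO clone 4 was left out (adjusted p up to 0.109). Other shifts belonged to some clones: -0.42 on chromosome 7 in KO clone 1, -0.37 on chromosome 8 and -0.30 on chromosome 13 in KO clone 2 (0.32, 0.21 and 0.25 on chromosome 13 in KO clones 1, 3 and 4), -0.27 on chromosome 19 in KO clone 4. The X chromosome stood at -0.26 and -0.17 in KO clones 1 and 2 and at 0.42 and 0.41 in KO clones 3 and 4. Of 84 chromosome medians in the KO clones 18 were beyond 0.25 in size, and none of those in the control libraries, whose largest was 0.10. With a preset correlation 9 chromosomes passed, with an estimated one 0 of 21 did (1 at an unadjusted p under 0.05). Of the 723 changed genes, 502 still passed when each library's chromosome medians were taken out, a fit chosen after seeing the data, which called 612 genes in all. Among the genes named above, Ifi27, Greb1, Clcf1, Tnfrsf14, Klf10, Phlda1, Mdm2, Axl, Itga5, Col6a1, Ddx3y and Uty no longer passed in that fit (adjusted p between 0.0561 and 0.695). Esrp2, Ehf, Lamb1, Itgb6, Foxg1, Sel1l and Mthfd2, which the list counts above include, did not pass in it either.

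**Figure D4:**
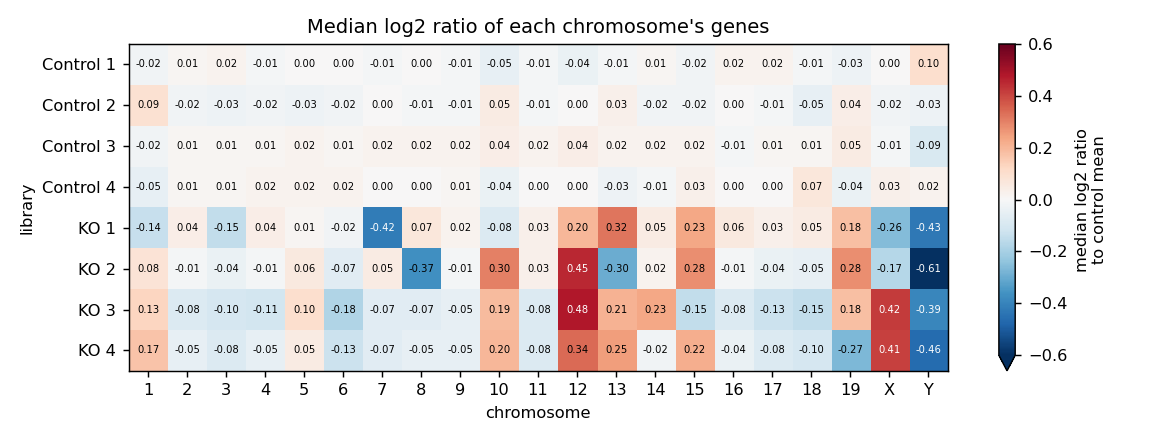
Median log2 ratio of the genes of each chromosome (columns) to the control mean in each library (rows), over genes with a mean of at least 5 CPM; red is higher and blue lower, and values are printed in the cells. Chromosome 12 is between 0.20 and 0.48 in the KO clones, and the control libraries stay within 0.10.

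The KO clones also differed more from each other than the control libraries did. The median SD of log2 CPM over tested genes was 0.276 among the KO clones and 0.133 among the control libraries, a ratio of 2.08, and it was larger in the KO clones for 80.5% of genes. Pearson's r across genes, which are not independent replicates, was 0.955 to 0.982 between KO clones, 0.987 to 0.993 between control libraries and 0.956 to 0.969 between the groups. KO clones 3 and 4 were the closest KO pair (0.982), with the next pair, KO clones 1 and 4, at 0.970. KO clones 3 and 4 also shared X chromosome medians of 0.42 and 0.41. Whether the 4 clones arose independently is not settled. All 4 lacked transcripts of the same 12 genes and had higher chromosome 12 medians, and a shared founder cell stays open below. The p-values take the 4 clones as independent, so they would overstate the evidence for changes inherited from such a founder. The first principal component held 43.1% of the variance and separated the groups, and the second held 22.3% and separated KO clones 1 and 2 from each other.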

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

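The spread test in this part was chosen before its results were seen. In 16 of 160 groups of 4 libraries, 1 library lay so far from the other 3 that its gap, as a share of the group's range, exceeded Dixon's 95% value for 4 libraries; chance gives about 1 in 20 groups, or 8.

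Among the control libraries, library 4 held 24.4 CPM of Asf1b against 16.8 to 17.4 in the others (share 0.92). Control library 2 held 1.53 CPM of Tspan32 against 0.442 to 0.568 (0.88). The same library was lowest in the list means of MHC class I genes (-0.075 against 0.022 to 0.027, share 0.95), senescence genes (-0.186 against 0.035 to 0.079, share 0.83) and endothelial markers (-0.241 against 0.044 to 0.101, share 0.83). Its chromosome 2 median was -0.0208, with the others at 0.00567 to 0.00788 (0.92).

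KO clone 2 held 89.8 CPM of Nrep against 175 to 183 in the other clones (share 0.91) and 37.2 CPM of Man1a against 14.1 to 17.3 (0.86). Its list mean was 0.15 for MHC class I genes against -0.531 to -0.417 (0.83), and 0.435 for endothelial markers against 0.087 to 0.137 (0.86). KO clone 3 had a chromosome 15 median of -0.145 against 0.223 to 0.282 (0.86). In 5 lost genes a share of 1 rests on 1 or 2 reads in a single clone: Serpina1a and Serpina1e in KO clone 2 (0.0418 CPM each), Serpina1d in KO clone 1 (0.037), Bche in KO clone 3 (0.0392) and Zfp37 in KO clone 2 (0.0836), the other clones being at 0. No explanation was tested for these single libraries.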

How the results depend on the processing

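Fits with chromosome medians removed and without chromosome 12 genes were chosen after the data were seen. They called 612 and 546 genes against 723. The count stayed within 1.5 times of 723 with limma-voom, group quality weights, RLE factors, library totals and both other filters (655 to 780). DESeq2 called 1623 genes, 846 higher and 777 lower, 616 at least 2-fold; the cause was not tested. Leaving out 1 library gave 150 to 1901 genes (65 to 1111 higher, 85 to 790 lower, 109 to 658 at least 2-fold), lowest without control library 1 and highest without KO clone 1. A threshold of 0.01 left 124 genes, by construction.

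The 6 libraries numbered 1 to 3 gave 51 genes with the number as a block (16 higher, 35 lower, 51 at least 2-fold) and 62 without the block (23 higher, 39 lower, 51 at least 2-fold), from fewer libraries. Deviations of libraries with the same number correlated across genes at 0.048, -0.072 and -0.065, and those with different numbers at -0.107 to 0.18. The numbers thus gave no sign of pairing, though so few pairs cannot exclude a weak one. Csf2 missed the threshold in those fits (adjusted p up to 0.192).

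Of 28 lists, 7 passed. DESeq2 gave 13 and no low-count filter 11, each of 31 lists; 2 of these (Y-linked genes, fibroblast and pericyte markers) had too few tested genes in the main test, which leaves 11 and 9 of the 28, a rise whose cause was not tested. The 6 libraries without a block gave 4. Fry gave 2 and an estimated correlation 0 (2 at an unadjusted p under 0.05). With an estimated correlation 0 chromosomes and 0 Reactome sets passed (1 and 18 at an unadjusted p under 0.05). Reactome sets past the threshold ran from 32 to 79 when 1 library was left out.

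Asf1a stayed short of the threshold, between -0.42 and 0.29 (adjusted p 0.391 to 0.998). Over 1392 alternatives of the 78 named genes past the threshold, 1003 kept direction and call and 388 only the direction. Uty alone changed sign, to 0.07 with chromosome medians removed, which by construction takes out a shift shared by the Y genes. Simulated 1.5-fold changes were recovered in 8 and 16 of 67 genes (11.9% and 23.9%, 1 run each), so changes of that size were often missed there. Fewer genes were changed in the simulated counts than were called in the data. That makes the adjustment stricter, so these shares need not hold for the data.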

Other observations

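The tests of a Serpina1 cluster deletion, of chromosome 13 copy number and of S phase, and the fit with chromosome medians removed, were chosen after results had been seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 723 changed genes, and the highest other gave 0. Every other split mixes KO clones with control libraries, so a difference between the groups widens the spread within it. The smallest share possible is 1 of 35, so the splits alone cannot exclude a chance division. Nor do they part loss of Asf1a from the picking of single clones, since the KO group holds both. Of the 723 genes, 69.4% still passed with chromosome medians removed. That share lies between the bounds of 50% and 75% set beforehand, so the part that copy number may play in the count stays open.

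In 12 genes, transcripts lay below 0.1 CPM in all 4 KO clones and above 1 CPM in all 4 control libraries, and 0 genes showed the reverse. Outside the Serpina1 cluster, Galnt12, Zfp37, Wdr31, Tut4 and Ago1 lie on chromosome 4, which holds 807 of the 13770 tested genes. Zfp2, Nid2 and Zfp532 lie on chromosomes 11, 14 and 18. What the grouping on chromosome 4 reflects was not tested. Deletions reaching the neighbours are argued against outside the Serpina1 cluster: the nearest tested neighbours had a median log2 fold change of 0.07 (quartiles -0.05 to 0.19, 16 genes). The exception was Ube2e2, 857 kb from Nid2, at -4.47, and a deletion there stays open. Neighbours lay up to 2284.8 kb away, so smaller deletions, of a lost gene alone or with untested genes, could not be seen and stay open. For the Serpina1 cluster the median of the neighbours was -10.54, but those neighbours belong to the pattern, and genes outside the cluster (Ifi27l2b -0.17, Dicer1 0.37) did not pass, so a deletion of the cluster stays open. A shared founder cell also stays open: 16.7% of the 72 genes off in any KO clone were off in all 4 (95% interval 8.9 to 27.3), under a bound of 50% that was wrong, since later losses in single clones say nothing of the 12 shared ones, where independence predicts 9.02e-07. That loss of Asf1a may silence these genes is a hypothesis with no test here, since the design cannot tell it apart from such a founder.

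Replication-dependent histone transcripts rose in all 4 KO clones. More non-polyadenylated RNA by as much as the histone rise is argued against, as 62 other tested RNAs of that kind had a median of 0.17 (0.12 to 0.31). Of these, 45 were higher and 0 passed the threshold, so a smaller rise of such RNA stays open. The 62 RNAs differed from the histone genes (permutation p = 1e-05, the smallest 100000 permutations can give). The interval and the permutation take genes as units, which are not independent replicates. Many of these RNAs lie in introns of host genes, which also limits this test. The library kit is not given, and whether the histone reads came from transcripts with or without a poly(A) tail was not tested. Copy number of the whole chromosome 13, which holds 12 of the 15 genes, is argued against in size: its medians were 0.32, -0.30, 0.21 and 0.25 in KO clones 1 to 4, and the 12 genes exceeded them by 0.94 (0.56 to 1.32), 1.71, 1.37 and 2.07 (the 3 genes elsewhere had means of 0.03, 1.73, 0.82 and 1.12). More cells in S phase would raise the G1/S list, whose median was -0.18 (-0.23 to -0.14 over resampled genes, which are not independent replicates). Camera with an estimated correlation gave that list an adjusted p of 0.767. Its mean log2 ratio was -0.346, -0.368 and -0.255 in KO clones 2 to 4, which argues against S phase there. In KO clone 1 it was 0.164, so S phase stays open in that clone. That loss of a chaperone of H3-H4 may raise these transcripts is a hypothesis with no test here, since KO and single-cell cloning coincide, and a gain of the histone clusters alone was not tested either.

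Chromosome 12 genes were higher in each KO clone. After a fit on GC content and exon length the mean shift was 0.37 (0.22 to 0.47 over the clones), so these biases are argued against. All of the 12 bins of 10 Mb had a mean over the KO clones above 0.15, or 100% (interval 73.5 to 100), which argues against a few loci. The interval takes bins as units, which share the same clones and are not independent replicates. In KO clone 1 alone some bins lay below 0.15, the lowest at 0.10 (40 to 50 Mb). An extra copy in a shared founder was not tested apart from Asf1a loss; its smallest shift, 0.196, just missed the bound of 0.2 set beforehand, and both may apply.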
